A study of Mus musculus with 6 samples.

How the data were processed

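Whole lungs of mouse embryos at embryonic day 14.5 were profiled on 6 arrays, 3 from control embryos that carried Shh-cre alone and 3 from mutant embryos in which Shh-cre deleted Foxp1 and Foxp4. Per the labels' protocols, total RNA was extracted with a silica column kit, reverse transcribed from a poly(T) primer carrying a T7 promoter, amplified by in vitro transcription and labelled with biotin. The array type, the genome build, the annotation version and the software version are not given in the sources used here. The design text states separate embryos, so p-values measure the spread between embryos of a group.

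The deposited values are log2 expression per probe set, made with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes) per the submitters' processing notes. The deposited log2 values come in 2 tables, whose 6 columns of array values were identical for all 28815 probe sets. The table with annotation also holds the authors' own comparison of mutant with control: a signed fold and a difference score, a false discovery rate as a q-value in percent, and an unadjusted p-value, per the file headers. The authors' test is not given in the sources used here. Array columns of the matrix table were matched to samples through their labels.

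Each probe set took its gene symbol from the annotation columns of the deposited table, updated through the reference gene table of assembly GRCm38.p6. Of the 28815 probe sets, 25528 had 1 gene symbol, 0 had several and 3287 had none. Names were matched by RefSeq accession for 20529 probe sets, by gene ID for 1524, by the current symbol for 1842 and by an older symbol for 545, and the name in the deposited table was kept for 1088. The update changed 3641 symbols, and 21956 distinct symbols resulted. The annotation text of the deposited table is cut short within long entries, so further genes of a probe set can be missing. Another 695 probe sets held the same 6 values as some other probe set. No coordinates of the reference are printed, because the build behind the deposited table is not stated; it was used for names, chromosomes and gene order.

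Differences between mutant and control arrays were fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate, no filter on dim probe sets), with Benjamini-Hochberg adjustment over all 28815 probe sets and a threshold of adjusted p under 0.05. A log2 change is mutant minus control. For Foxp1, Foxp2, Foxp4 and Agr2 a 2-sided exact permutation test of 3 against 3 values was added, whose smallest possible p is 0.1. The genes named were the 12 with the highest and the 12 with the lowest log2 change among probe sets with 1 symbol that passed the threshold and whose mutant values all lay on 1 side of the control values, 1 probe set per symbol. Predicted genes with Gm, Rik or LOC names and small RNA genes were counted but not named by this rule; LOC280487 and Gm4638 were named after their values were seen, and 2 genes that the rule names are not reported here. Foxp1, Foxp2, Foxp4 and Agr2 were added, with up to 5 members of each gene list with the smallest p and the members needed to describe its best known markers.

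A total of 33 gene lists were tested with camera (limma, preset inter-gene correlation 0.01, 2-sided), on 1 probe set per gene symbol, the one with the highest mean over all 6 arrays, with Benjamini-Hochberg adjustment over the lists. They cover goblet, club, ciliated, basal and neuroendocrine cells, alveolar type 1 and type 2 cells, progenitors, epithelium in general, stomach and intestine, protein folding, signalling pathways, the cell cycle, the Foxp family, other cell types a lung sample can hold, and sample quality. Members of a list were also counted with adjustment over the list alone. Camera with an estimated correlation and fry were run as alternatives. Medians of the lists were set against 10000 random lists matched on mean expression. The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives added afterwards are cyclic loess normalization, counting identical probe sets once, and leaving out chromosomes 6 and 17. The comparison with matched random lists was also added afterwards.

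The other alternatives were the replicate number as a block, eBayes with a trend and robust fitting, filters on dim probe sets at the 30th percentile and at the median, repeated quantile normalization, median centring, array weights, a threshold of 0.1, a fold of at least 1.5, 1 probe set per symbol, a Welch test, and leaving out each array in turn. Arrays were compared pairwise before averaging, and between 9 and 24 of the 28815 values were identical for any pair, so none was a copy of another. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

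The fit was tested on simulated data for the comparison of mutant with control, with 200 of 28815 probe sets changed by known folds. It recovered 49.2% of 65 probe sets changed 1.25-fold, 98.6% of 70 changed 1.5-fold and 100% of 65 changed 2-fold. It called 11 unchanged probe sets and none of the changed ones in the wrong direction. Of 100 unshifted random lists, 2 had a camera p under 0.05. The simulated noise was normal, with the variance that eBayes estimated for each probe set, and the probe sets were independent of each other. The recovery holds for these settings and can be lower on the real arrays. The simulation also does not check camera where the genes of a list are correlated.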

Results

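Gene expression was measured in whole lungs of mouse embryos at stage E14.5, on 3 arrays of Shh-cre control lungs and 3 arrays of mutant lungs lacking Foxp1 and Foxp4, a pair of forkhead transcription factors, where Shh-cre is active. Shh-cre recombines floxed genes in the epithelium of the developing lung. The array medians lay between 8.21 and 8.23 on the log2 scale, and any pair of arrays correlated at 0.995 to 0.998 across probe sets. The lowest values, 0.9947 to 0.9963, were those of control 3 with the mutants. Control 1 correlated with control 3 at 0.9967, below its 0.9971 to 0.9975 with the mutants. Control 2 correlated with control 3 at 0.9977, above its 0.9965 to 0.9974 with the mutants. The median residual SD of a probe set was 0.07, and the 3 arrays per group limit the precision. Xist, the transcript of the inactive X chromosome, stood at 12.83 in control 3 and between 6.00 and 6.23 in the other 5 arrays, while the Y-linked Ddx3y stood at 5.89 in control 3 and between 9.45 and 10.64 elsewhere. This is the pattern of a female embryo in control 3 and of male embryos elsewhere, so sex was not balanced between the groups. The labels give no sex. The design asks how loss of Foxp1 and Foxp4 alters gene expression with regard to secretory differentiation of the lung epithelium.

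Of the targeted genes, Foxp4 fell in mutant lungs, from 10.21 ± 0.05 in controls to 9.80 ± 0.03 in mutants (log2 mean ± SD, n = 3 each), a log2 change of -0.41 (SE 0.05, limma adjusted p = 0.0190). Foxp1 measured 10.91 ± 0.03 in controls and 10.64 ± 0.07 in mutants, a log2 change of -0.27 (SE 0.05) that did not pass (adjusted p = 0.0884). The related Foxp2 had a log2 change of 0.21 (adjusted p = 0.121) and Foxp3 one of -0.15 (adjusted p = 0.307). In the authors' deposited comparison, whose test is not given, Foxp1 was lower with a q of 3.70% and Foxp2 higher with a q of 2.11%, both under 5%. For each of Foxp1, Foxp2 and Foxp4 the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 values allow. Adjusted over the list alone, 3 of the 4 Foxp genes fell and 1 rose, against 1 that fell over all probe sets. The camera test of the Foxp list did not pass (adjusted p = 0.0617, and adjusted p = 0.728 with an estimated correlation), and fry gave an adjusted p of 0.00605. The probe sets can lie outside the deleted exons and whole lung holds cells without recombination, so these values do not check the labels. The Foxp4 call ended without control 2 (adjusted p = 0.0797), mutant 2 (0.0876) or mutant 3 (0.0535), while Foxp1 passed with a trended robust prior (0.0293) and with array weights (0.0127).

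Across the whole array, Habp2, a hyaluronan-binding serine protease, rose most, from 8.53 ± 0.11 to 10.81 ± 0.08, or 4.85-fold (log2 change 2.28, SE 0.07, adjusted p = 2.55e-05). Tecrl, an enoyl reductase-like gene, rose 3.55-fold, and Agr2, an endoplasmic reticulum protein disulfide isomerase of mucus-producing cells, rose 2.53-fold. Hdc, which makes histamine, and Cpa3, a carboxypeptidase of mast cell granules, rose 2.32-fold and 2.29-fold (adjusted p = 0.0164 and 0.0301). The potassium channel Kcnj13 rose 2.11-fold and the tight junction gene Cldn8 rose 2.07-fold. Gmnc and Deup1, both of the multiciliated cell programme, had log2 changes of 0.97 (adjusted p = 0.0301) and 0.90 (0.0480), calls that ended in 5 and in all 6 of the fits without 1 array. The remaining highest genes were Apela, a peptide ligand of the apelin receptor (log2 change 0.99), Bend6 (0.90) and the protocadherin Pcdh10 (0.81).

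Among genes that fell, the predicted gene EG665955 had the lowest change, from 11.10 ± 0.15 to 5.91 ± 0.33 (log2 change -5.19, SE 0.16, adjusted p = 2.55e-05). This was 1 of its 5 probe sets, and the others, which share 1 set of values, had a log2 change of -1.63 (adjusted p = 0.107), and neither repeats or strain differences under its probes nor whether the mutant value lies above background were checked. Cthrc1, a secreted matrix-associated protein, fell 2.77-fold (log2 change -1.47, adjusted p = 0.00119), and Cym, the protease chymosin, fell 2.53-fold from a bright 12.62 ± 0.16 (adjusted p = 0.0125). Lamp3, a lysosomal membrane protein of alveolar type 2 cells, had a log2 change of -1.08 (adjusted p = 0.0232). Cps1, a urea cycle enzyme, fell by 0.91 on the log2 scale. The other lowest genes were Cpq (log2 change -0.82), Serinc2 (-0.80), Art4 (-0.80), the calcification inhibitor Mgp (-0.76), Smco3 (-0.73) and the sialyltransferase St6gal2 (-0.68). Smco3, Art4 and Mgp are neighbours on chromosome 6, and St6gal2 lies 38 measured genes from Foxp4 on chromosome 17.

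**Figure D1:**
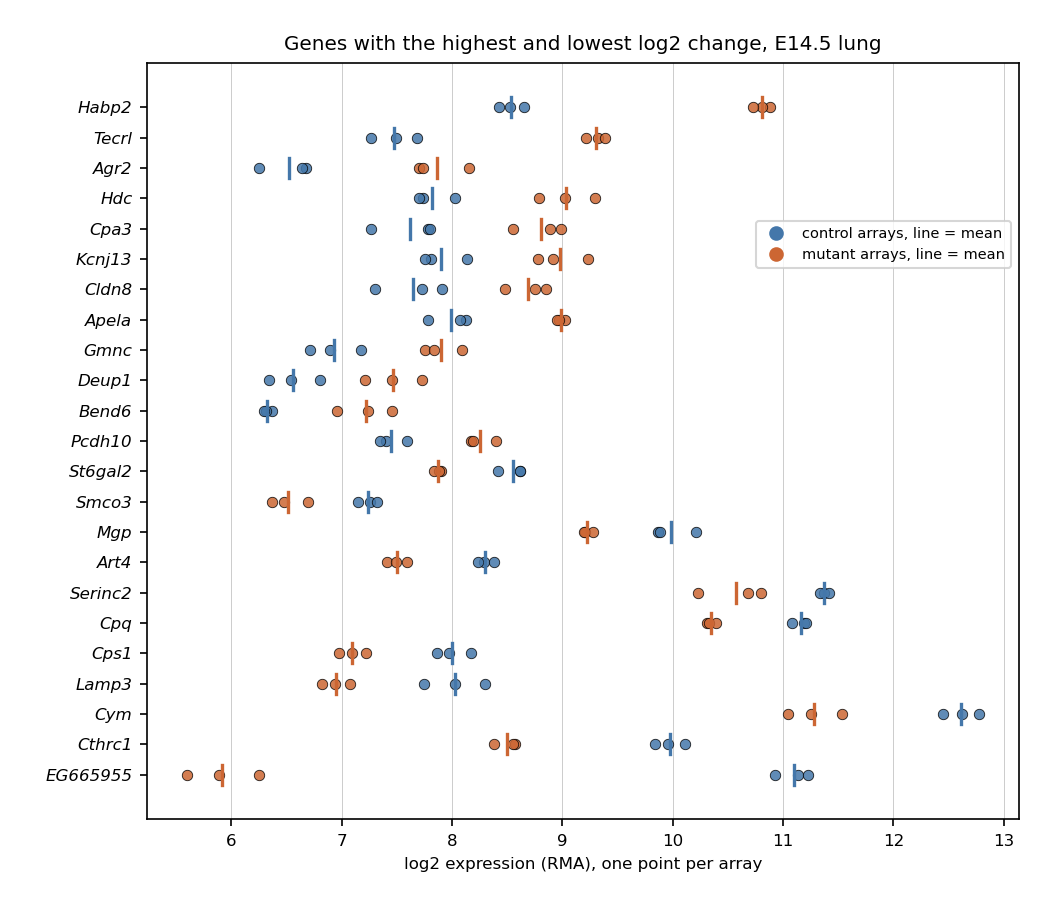
Log2 expression (horizontal axis) of the 12 genes with the highest and 11 of the 12 with the lowest log2 change, 1 point per array, blue for the 3 control and orange for the 3 mutant arrays, with a line at each group mean. For every gene shown the groups do not overlap, with Habp2 near 8.53 in controls and 10.81 in mutants.

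In total 223 of 28815 probe sets changed (limma, adjusted p under 0.05), 148 higher and 75 lower in mutants, for 150 gene symbols of which 79 rose and 71 fell. The median size of these changes was 0.57 on the log2 scale, and 9 gene symbols rose and 4 fell more than 2-fold. The 9 include LOC280487 and Gm4638, which share 1 set of values. At an unadjusted p under 0.05 there were 3393 probe sets. The groups did not overlap for any of the 223, and over all probe sets this held for 18%, where chance gives 10%. Among the higher probe sets 64 held the same values as another probe set. Of these, 50 carried 1 identical set of values, annotated to LOC280487, a retroviral pol polyprotein, and to Gm4638. These 50 rose 2.60-fold (7.29 ± 0.16 to 8.67 ± 0.45, limma adjusted p = 0.0301), and for these too repeats and strain differences were not checked. The authors' deposited table had 496 probe sets with a q under 5%, 303 higher and 193 lower, and all 223 were among them. The count fell to 18 without control 2, 102 without control 3, 136 without mutant 1, 11 without mutant 2 and 147 without mutant 3, and to 138 with identical probe sets counted once. Of 43 called genes named in the text, 11 passed without control 2, 7 without mutant 2 and 23 to 33 without each of the other arrays, and none reversed. Habp2, Tecrl, Dkk1, EG665955, Cthrc1, Cpq and Art4 passed in all 6 of these fits, while Areg, Deup1, Elf5 and Itgb6 passed in 0 of the 6 and 9 genes, Gmnc, Krt19, Aldh1a7, Sp5 and Serinc2 among them, in 1 (limma).

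Genes of goblet and mucous secretory cells, the class closest to the question of the study, did not move together. Of 38 measured members 1 rose, Agr2, from 6.52 ± 0.23 to 7.86 ± 0.25 (log2 change 1.34, SE 0.15, adjusted p = 0.0157), 0 fell and 37 did not pass, and adjusted over the list alone 1 rose and 1 fell. The cell surface mucin Muc1 had a log2 change of -0.54 (adjusted p = 0.0689). The gel-forming mucins Muc5ac and Muc5b had log2 changes of -0.23 and -0.09 (adjusted p = 0.363 and 0.506), and Spdef, the transcription factor of goblet cells, one of 0.06 (0.737). The median of the list was -0.04, at percentile 51.6 of matched random lists, and camera gave an adjusted p of 0.437 (0.761 with an estimated correlation). The list is dim (mean 7.28, against 8.21 for the median probe set), and no detection values were used. Changes of members with little signal could be missed, so the lack of calls does not show that these genes did not respond. The Agr2 call ended without control 2 (adjusted p = 0.0648) or mutant 2 (0.0608), and its exact permutation p was 0.1.

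Of 25 club cell genes 1 fell, the retinaldehyde-metabolising family member Aldh1a7 (log2 change -0.44, adjusted p = 0.0481), 0 rose and 24 did not pass, while 4 fell adjusted over the list alone. The secretoglobin Scgb3a2 went from 7.42 to 6.67 (log2 change -0.76, adjusted p = 0.0699) and the carbonyl reductase Cbr2 from 7.89 to 7.05 (-0.83, 0.201). Krt15 had a log2 change of -0.27 (adjusted p = 0.110). Scgb1a1, the classical club cell product, stood at 4.96 in controls and 4.98 in mutants, near the lower end of the array. The list did not pass camera (adjusted p = 0.0510, and 0.728 with an estimated correlation), but did with the filter at the 30th percentile (0.0170), median centring (0.0463), the replicate block (0.0496) or without control 2 (0.0214).

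Ciliated cell genes lay higher in mutants. Of 29 members 1 rose, Gmnc, and adjusted over the list alone 3 rose, with the centriole-amplification gene Ccno at a log2 change of 0.34 (adjusted p = 0.114) and the dynein light chain Dynlrb2 at 0.28 (0.151). Foxj1, the regulator of motile cilia, had a log2 change of 0.14 (adjusted p = 0.477). The median of the list was 0.04, or 0.06 without control 3, with 18 of 29 members above 0, and camera gave an adjusted p of 9.99e-04 (adjusted p = 0.728 with an estimated correlation). Neuroendocrine genes lay lower, with 20 of 23 members below 0 and a median of -0.10, or -0.06 without control 3, at percentiles 0.34 and 2.15 of matched random lists. The list is dim (mean 7.65), and the dim lists of thymus, of skeletal muscle and oesophagus, and of nerve had medians of -0.11, -0.11 and -0.12. Of the 23 members 1 fell, and adjusted over the list alone 4 fell, with the prohormone convertase Pcsk1 at a log2 change of -0.26 (adjusted p = 0.101) and Insm1 at -0.30 (0.211). Camera gave an adjusted p of 9.99e-04 for this list too (adjusted p = 0.728 with an estimated correlation).

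Among alveolar type 2 genes 1 of 21 fell, Lamp3, and adjusted over the list alone 5 rose and 5 fell. The phosphate transporter Slc34a2 had a log2 change of 0.64 (adjusted p = 0.143), the surfactant protein gene Sftpc one of 0.38 (0.212) and the lipid transporter Abca3 one of 0.27 (0.193). A second, dimmer Abca3 probe set had a log2 change of 0.04 (limma adjusted p = 0.800). The median was 0.05 and the mean -0.01, and the list did not pass (camera adjusted p = 0.179). Its median lay at percentile 99.6 of matched random lists, with and without control 3. Of 18 alveolar type 1 genes 0 passed (limma, 5 at an unadjusted p under 0.05), and adjusted over the list alone 1 rose and 2 fell, with Hopx at a log2 change of -0.28 (adjusted p = 0.102) and Akap5 at -0.36 (0.180). The median of that list was 0.03 and its mean -0.00394, and camera gave an adjusted p of 0.530. Basal cell genes had 11 of 12 members below 0 with 0 that passed (1 at an unadjusted p under 0.05), among them the keratin Krt5 at -0.15 (adjusted p = 0.280), and camera gave an adjusted p of 0.0607.

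Markers of the epithelium and its progenitors changed little as groups. Among 21 proximal airway progenitor genes 2 fell, the keratin Krt19 (log2 change -0.42, adjusted p = 0.0382) and the transcription factor Elf5 (-0.32, 0.0323), and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.219). Among 27 genes of epithelium in general 2 fell, Krt19 again among them, with 2 that fell adjusted over the list alone, and the median was 0.03 with a mean of -0.00496 (camera adjusted p = 0.176). That small median still lay at percentile 98.2 of matched random lists, or 98.4 without control 3. Of 20 distal tip progenitor genes 0 passed (limma, 7 at an unadjusted p under 0.05), and adjusted over the list alone 2 rose and 1 fell, with the chaperone Clu at -0.31 (adjusted p = 0.0910). The tip list had a median of -0.00696 and a mean of 0.00489 (camera adjusted p = 0.437). Among 32 stomach and intestine genes 1 rose, the gastric junction gene Vsig1 (log2 change 0.67, adjusted p = 0.0157), which was also the count adjusted over the list alone, while 27 of 32 lay below 0 (camera adjusted p = 0.179, but 0.0392 with the filter at the 30th percentile and 0.0165 without control 1).

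Among 24 Wnt pathway genes the secreted antagonist Dkk1 rose from 7.69 ± 0.09 to 8.41 ± 0.10 (log2 change 0.71, SE 0.07, adjusted p = 0.0127) and the target gene Sp5 rose by 0.33 on the log2 scale (adjusted p = 0.0301). Adjusted over the list alone 3 rose and 2 fell, with the Wnt deacylase Notum at 0.27 (adjusted p = 0.131) and the antagonist Sfrp1 at -0.30 (0.142), and camera gave an adjusted p of 0.998. A second Notum probe set of similar mean had a log2 change of -0.02 (limma adjusted p = 0.950). Of 14 hedgehog pathway genes 0 passed, also at an unadjusted p under 0.05, with Gas1 at -0.12 (limma adjusted p = 0.439) and a camera adjusted p of 0.595. Of 22 Notch pathway genes 0 passed (3 at an unadjusted p under 0.05), with the feedback gene Nrarp at -0.22 (limma adjusted p = 0.172), and camera gave an adjusted p of 0.533 with a median of -0.00125 and a mean of 0.00730. Of 32 cell cycle genes 0 passed and 1 fell adjusted over the list alone, the ribonucleotide reductase subunit Rrm2 (log2 change -0.24, adjusted p = 0.0793), with a camera adjusted p of 0.484. Genes of endoplasmic reticulum folding lay higher, with 21 of 32 above 0 and a median of 0.03, but 0 members passed (limma, 5 at an unadjusted p under 0.05). The smallest p was that of Creld2, with a log2 change of 0.16 (adjusted p = 0.256). Camera gave this list an adjusted p of 0.0204, and an adjusted p of 0.728 with an estimated correlation. Its call ended without control 3 (adjusted p = 0.167), mutant 1 (0.0664) or mutant 3 (0.0628), and with quantile normalization (0.0691), array weights (0.0612) or cyclic loess (0.0694).

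Lists of other cell types also differed slightly. Mesothelial genes lay lower, with 10 of 12 below 0 and a median of -0.16, and 1 fell, Krt19, against 3 adjusted over the list alone, including the membrane glycoprotein Gpm6a at -0.26 (adjusted p = 0.172) and the retinoic acid-synthesising enzyme Aldh1a2 at -0.34 (0.215). Smooth muscle genes lay higher, with 12 of 14 above 0 and a median of 0.05, and 0 passed (1 at an unadjusted p under 0.05). Camera gave adjusted p of 0.0134 for mesothelium and 0.0204 for smooth muscle, and with an estimated correlation an adjusted p of 0.728 for each. Lists of thymus, of skeletal muscle and oesophagus, and of thyroid and trachea cartilage lay lower (camera adjusted p = 0.0204, 0.0305 and 0.0272), again with an adjusted p of 0.728 with an estimated correlation. In these 3 lists 0 members passed (limma, with 2, 6 and 6 at an unadjusted p under 0.05), and 2 cartilage genes fell adjusted over the list alone. At dim probe sets control 3 deviated from the median over the 6 arrays by a median of 0.0525, against -0.0236 to 0.0107 for the other arrays. Without control 3 the adjusted p of the lists became 0.282, 0.488 and 0.349, and that of smooth muscle 0.144. Without mutant 3 the calls of the 3 lists ended too (adjusted p = 0.0787, 0.0787 and 0.0763), as they did with cyclic loess (0.0533, 0.0694 and 0.0533, and 0.0533 for smooth muscle). The skeletal muscle list also lost its call with the filter at the 30th percentile (0.376), quantile normalization (0.0691) and array weights (0.138), and the cartilage list with array weights (0.136) and without mutant 1 (0.0541).

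The remaining lists of other cells did not pass, with camera adjusted p of 0.0510 for lung mesenchyme, where 19 of 21 genes lay below 0 and Col1a1 had a log2 change of -0.28 (adjusted p = 0.294), 0.580 for endothelium, 0.0617 for red blood cells, 0.0996 for macrophages and other leukocytes, 0.179 for heart muscle, 0.0996 for liver and 0.0596 for nerve and neural crest. No member of these lists passed in limma, and at an unadjusted p under 0.05 there were 5, 0, 2, 1, 0, 4 and 3 members. The mesenchyme list passed with the replicate block (camera adjusted p = 0.0403), the filter at the 30th percentile (0.0392), quantile normalization (0.0425), median centring (0.0463), cyclic loess (0.0344) and without mutant 1 (0.0296). The lists of nerve, liver, leukocytes, red blood cells and heart each passed in at least 1 alternative, with the lowest adjusted p 0.0134, 0.0140, 0.0158, 2.67e-07 and 0.0337, the fourth of these without mutant 2. Among the quality lists, hypoxia genes lay higher with 14 of 20 above 0 and a median of 0.07 (camera adjusted p = 0.0204, and 0.728 with an estimated correlation), although 0 passed singly and Pdk1 had a log2 change of 0.24 (adjusted p = 0.180). The hypoxia call ended without control 1 (adjusted p = 0.0580), control 3 (0.0525) or mutant 1 (0.379), and with quantile normalization (0.0687), array weights (0.0947) or cyclic loess (0.0692). The lists of immediate early genes, housekeeping genes and embryo sex did not pass (camera adjusted p = 0.580, 0.571 and 0.116), the last of them passing without control 2 (0.0482). The embryo sex list joins Xist with Y-linked genes, which went in opposite directions, so camera cannot check with it whether sex was balanced. In all, 9 of 33 lists passed camera, 4 higher and 5 lower, and 0 passed with an estimated correlation. The adjusted p of 0.728 that many lists share there comes from the Benjamini-Hochberg step and does not rank them. With an estimated correlation, the unadjusted camera p of the 9 lists ran from 0.0499 for neuroendocrine to 0.344 for hypoxia genes. The neuroendocrine list was the only 1 of the 33 under 0.05. Fry passed 1 list, the Foxp family, which holds the targeted genes and is not among the 9. Of the 9 lists 0 passed fry, with adjusted p of 0.290 for ciliated, 0.0844 for neuroendocrine and 0.211 for mesothelial genes.

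**Figure D2:**
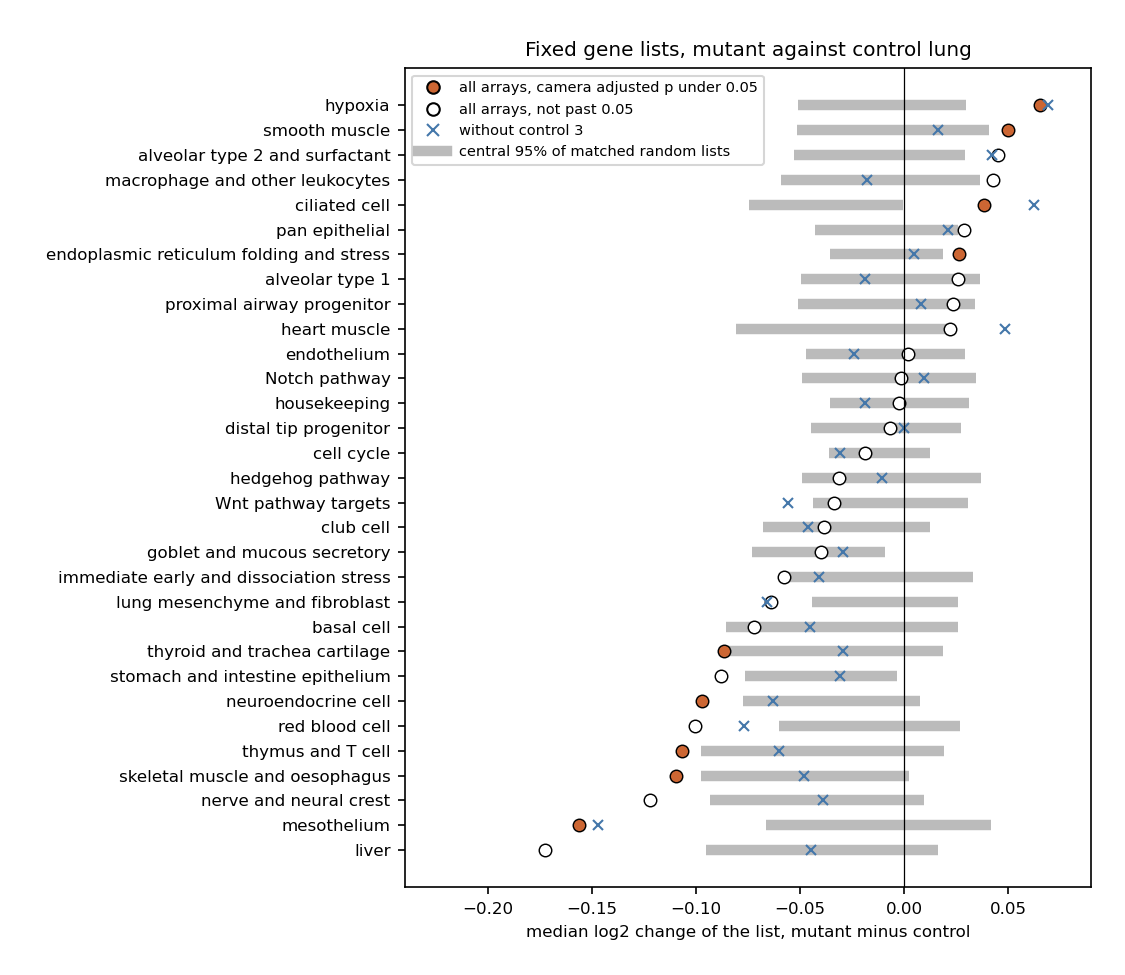
Median log2 change of each gene list (circles, mutant minus control), orange where camera gave an adjusted p under 0.05 with all 6 arrays, with grey bars for the central 95% of 10000 random lists matched on mean expression over the same arrays and crosses for the median without control 3. The lists of embryo sex and of the Foxp family are left out. The bars hold for all 6 arrays and not for the crosses. Against matched lists without control 3, the lists of thymus, of skeletal muscle and of cartilage lay at percentiles 7.24, 14.7 and 34.9. With all arrays they lay at 1.19, 0.62 and 2.79, the last inside its bar.

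Changed genes were placed unevenly along the chromosomes, as ordered in the reference gene table. Chromosome 6, which carries Foxp1, held 19 changed genes of 1162 (1.64%), of which 15 fell, among them Smco3, Art4 and Mgp. Chromosome 17, which carries Foxp4, held 8 of 1022 (0.783%), of which 7 fell, Foxp4 included. Its share was close to the 0.774% of all probe sets that changed, though that figure counts probe sets and not genes. Counted by gene, chromosome 14, which carries neither target, had the same share (0.783%). Chromosome 12, which carries neither target, held 9 of 658 (1.37%), of which 2 fell. Chromosome 15 held 13 of 800 (1.62%), of which 7 fell, among them Cthrc1 and Cpq. Within 100 measured genes on either side of Foxp1 and Foxp4 there were 11 changed genes besides the targets, 10 lower and 1 higher. The lower ones included the contactin Cntn4 (log2 change -0.68), Tspo2 (-0.57) and St6gal2 (-0.68), and the higher one was Enpp4 (0.42). Of the 11, 4 lay near Foxp1 and 7 near Foxp4, and neither region was tested alone. The 7 were all the changed genes of chromosome 17 besides Foxp4. Shifting all calls together along the gene order gave 11 or more in a share of 0.0189 of 21073 shifts, with a median of 2. This comparison was chosen after the positions were seen, and leaving out chromosomes 6 and 17 gave 183 changed probe sets, 135 higher and 48 lower.

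**Figure D3:**
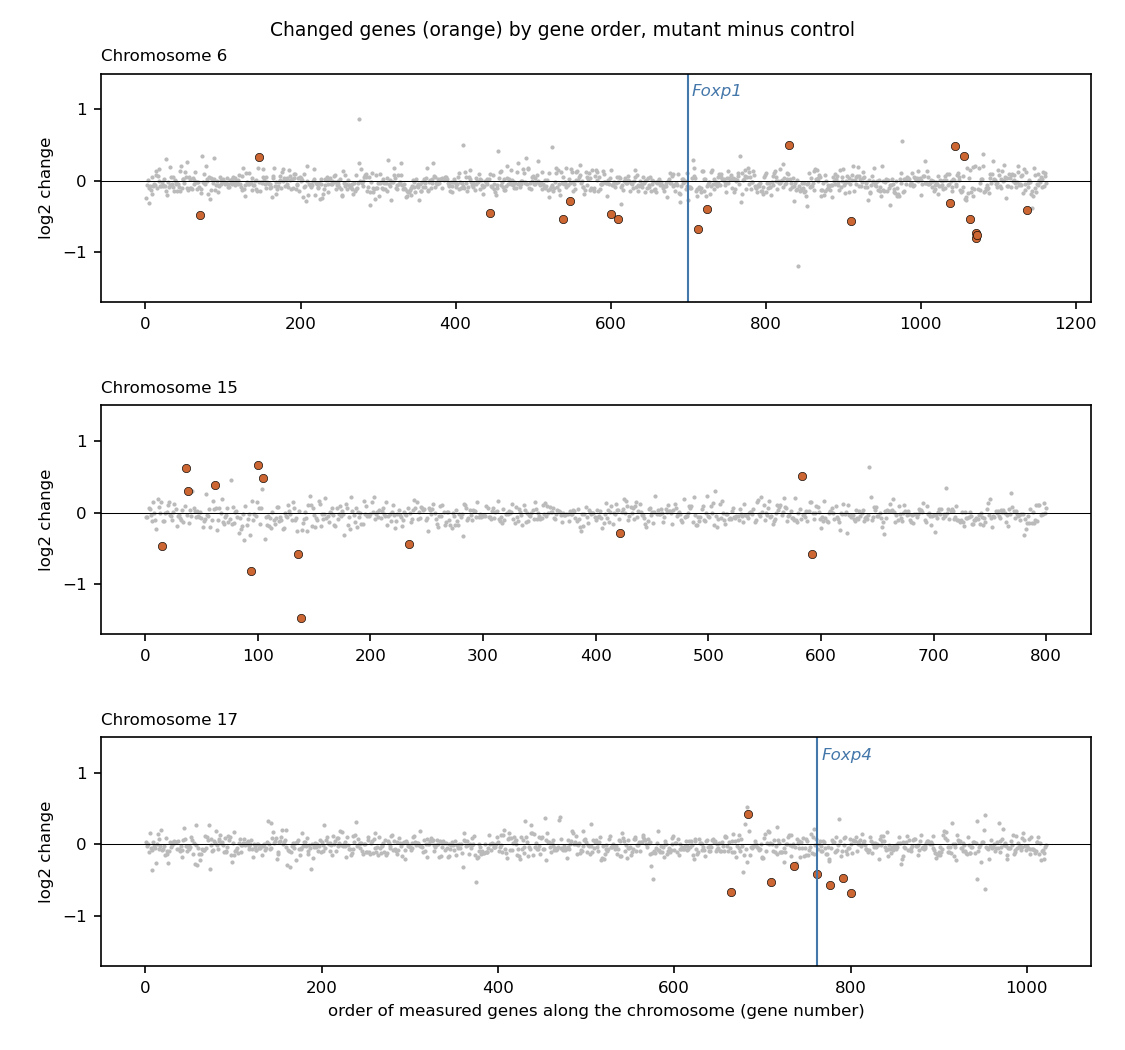
Log2 change (mutant minus control) of each measured gene in order along chromosomes 6, 15 and 17, grey for genes that did not pass and orange for the 19, 13 and 8 changed genes, with a blue line at Foxp1 and at Foxp4. On chromosome 17, 6 changed genes including Foxp4 fall within 1 window of 100 genes.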

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

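Cyclic loess, counting identical probe sets once and leaving out chromosomes 6 and 17 were chosen after the results were seen. The count of genes changed in mutant lungs, 223 with 148 higher and 75 lower, became 7, 4 and 3 with a replicate block, where 7 were shared. The sample titles do not say whether the replicate numbers pair the embryos. Deviations of arrays with the same number correlated at -0.194, 0.0395 and -0.185, and not every array correlated best with its own number. These are deviations from means of 3 arrays, so their correlations cannot exclude pairing. The counts became 1748, 848 and 900 with array weights, which gave control 2 a weight of 9.20, 360, 227 and 133 at an adjusted p under 0.1, and 107, 86 and 21 with a fold of at least 1.5, by construction of those thresholds. A Welch test called 0, 0 and 0, with 2231 probe sets at an unadjusted p under 0.05. Counting identical probe sets once gave 138, of which 73 were higher, 1 probe set per symbol left 81 higher, leaving out probe sets below the median left 88 higher, and without chromosomes 6 and 17 there were 48 lower, each with fewer probe sets tested. The trended robust prior gave 247, 136 and 111, with 164 shared, and the other settings moved these counts by less than 1.5 times. Leaving out each array in turn gave 11 to 152 changed, 7 to 107 higher and 4 to 63 lower. The fixed gene lists changed, 9 in all, became 14 with the replicate block, 0 with an estimated correlation, 1 with fry, 4 with cyclic loess and 3 to 15 when each array was left out, with 3 without control 3. The list that passed fry was the Foxp family, which is not among the 9. The ciliated, neuroendocrine and mesothelium lists passed in each of the 6 fits without 1 array. The goblet and mucous secretory list kept its direction and its side of the threshold in all alternatives, with adjusted p from 0.112 to 0.933. The log2 change of Foxp4 was -0.41 under the replicate block, where it no longer passed (adjusted p = 0.130, with a range of 0.00230 to 0.130 over all alternatives), and -0.43 to -0.38 without 1 array. That of Foxp1 was -0.27 with the trended robust prior and with array weights, where it passed, over a range of adjusted p from 0.0127 to 0.332. Scgb1a1, not called, reversed to -0.0512 with array weights and ran from -0.20 to 0.16 without 1 array. For shifts not explained by construction or by fewer arrays, the cause was not tested. The second deposited table holds identical values and gave no separate result. Genes near the lower end of the array, such as Scgb1a1 at about 4.96, may have little signal over background, which was not measured.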

Other observations

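Beyond the genes and lists already described, further changed genes are named here, chosen after their values were seen. Lamb3, a laminin chain of the epithelial basement membrane, fell by 0.52 on the log2 scale, and Itgb6, an epithelial integrin subunit, fell by 0.47. Areg, a ligand of the epidermal growth factor receptor, fell by 0.34, the guidance protein gene Ntn1 fell by 0.45 and the Wnt receptor Fzd6 fell by 0.57. Among genes that rose were Fgf1, a fibroblast growth factor (log2 change 0.69), Cubn, an endocytic receptor (0.69), Matn2, a matrix protein (0.66), the proprotein convertase Pcsk6 (0.64) and Rfx6, a transcription factor of gut and pancreatic endocrine cells (0.52). No theme was tested for these genes, and all 10 lost their call without control 2 and again without mutant 2. Itgb6 and Areg lost it in each of the 6 fits without 1 array, and Ntn1, Pcsk6 and Rfx6 in 5 of them.

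The tests in the next 3 paragraphs were chosen after the results were seen; the splits of the arrays were planned.

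The changed genes around Foxp1 and Foxp4 may reflect DNA of another strain that stayed linked to the floxed alleles, since the labels give a mixed C57BL/6 and 129X1,129S1 background and a sequence difference under a probe lowers its signal. Within 100 measured genes of the targets 11 genes were called, 10 of them lower (90.9%), against 56 of 127 called genes elsewhere (44.1%, 2-sided Fisher exact p = 0.00335), and the shift test gave 0.0189, or 0.0262 and 0.0441 for windows of 50 and 200 genes. These values pool both targets, with 4 called genes near Foxp1 and 7 near Foxp4, so they do not show a cluster at each target. A local effect of the deletions on adjacent genes stays open, because 0 of the 40 nearest genes were called in limma but 79.4% of shifts gave 0 too, and 8 of the 40 (20%) had an unadjusted p under 0.05 against 12.4% of all ordered genes. Effects over longer distances and a true response of these genes stay open as well. Dense windows without a target lay on chromosomes 6 (8 called of 100 genes, with Smco3, Art4 and Mgp) and 15 (7, with Cpq and Matn2). Both exceeded random placement (permutation p = 6e-04 and 0.0045). The window on chromosome 17 had 6 called (permutation p = 0.0498), but that count includes the targeted gene Foxp4 itself. The window was not tested without Foxp4, so this p cannot show clustering of the other called genes there.

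The lower medians of the lists of thymus, of skeletal muscle and oesophagus, and of thyroid and cartilage may reflect the higher dim values of control 3, since 0 of the 3 lists passed without it, but 0 passed without mutant 3 either (adjusted p = 0.0787, 0.0787 and 0.0763), so the loss is not particular to control 3. The median log2 change of the dimmer probe sets was -0.0364 with all arrays and -0.0119 without control 3. Neither this nor fewer cells of these other types in mutant samples can be excluded, and the explanations cannot be told apart, since 2 of the 3 lists lay below the 2.5th percentile of matched lists with all arrays, as that explanation asks, but 0 did without control 3. Control 3 is also the array with high Xist, so embryo sex stays open as an untested difference.

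Hdc and Cpa3 rose 2.32-fold and 2.29-fold, and more mast cells in mutant lungs are a candidate explanation. The median log2 change of 6 further mast cell genes, Cma1, Mcpt4, Tpsb2, Tpsab1, Ms4a2 and Fcer1a, was 0.0518, and the upper 95% limit was under 0.5 for each of the 6. These limits ran from 0.130 to 0.318, against log2 changes of 1.21 for Hdc and 1.19 for Cpa3. All 6 genes lie below the median probe set (8.21), with means from 4.90 to 7.43, and no detection values were used to tell whether their probe sets were above background, so more mast cells cannot be excluded. A change of Hdc and Cpa3 in other cells was not tested.

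The 223 changed probe sets came from 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, and the highest of the other splits gave 0 in limma (2960 at an unadjusted p under 0.05, against 3393). With 10 splits the share cannot go under 0.05.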
